A study of Canis lupus familiaris with 13 samples.

How the data were processed

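Heart tissue RNA of 13 separately named dog samples was measured on an Affymetrix canine array, with 1 array each. The samples were 3 of control mongrels, 3 of Dobermans and 4 of Boxers with dilated cardiomyopathy, and 3 of paced mongrels. The p-values measure the spread between samples within groups, pooled over all 4 groups, and not the spread of the compared groups alone. The groups varied unequally. The mean correlation of an array with its own group was 0.789 to 0.844 in the Dobermans and 0.947 to 0.969 on the other arrays. The deposited values are MAS5 signal intensities on a linear scale, with each array scaled by the authors to a common level; the 2% trimmed mean of each array lay near 500 when checked on the file. The version of MAS5 was not given in the sources used here. Signals ran from 0 to 95340, with 3 values of 0.

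The 77 control probe sets were set aside and used only to describe the arrays, which left 23836. Values were analysed as log2(signal + 16). Probe sets with a mean log2 value under the 40th percentile (6.95, a signal of 108) were left out, and 14302 were tested. The array annotation gave 10549 probe sets 1 gene symbol, 138 several and 13149 none; symbols were updated through the gene identifiers in the reference, and 0 changed. For gene lists and named genes, each gene was represented by the tested probe set with the highest mean signal, which gave 5242 genes, and results of some other probe sets are given beside it. No genome coordinates were used.

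A linear model with 1 mean per group was fitted to all 13 arrays in limma 3.58.1 (R 4.3.3), with 9 residual degrees of freedom, moderated variances with an intensity trend and Benjamini-Hochberg adjustment at 0.05 over the tested probe sets of each comparison. The comparisons were each of the diseased or paced groups with the controls, the Dobermans with the Boxers, and each breed with the paced mongrels. The comparison of Dobermans with Boxers tests the difference between the breeds directly. Where leaving out samples left 1 array in a group, the pooled spread was used, which assumes that the lone sample varies like the other groups. Fold changes are 2 to the power of the log2 change, and signals are means with SD of the deposited values. Where the mean signal of a group lies under the filter level, the size of a change depends on the pseudocount. Array measures were compared with exact permutation tests over all splits of the samples.

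Gene lists of muscle function, energy metabolism, cell types and stress responses, 29 in all, were written down before the data were examined, as were the grouping, the comparisons, the named genes and the alternatives, apart from those named below. The 28 lists with at least 5 tested genes were tested in limma with camera and a correlation estimated for each list, with a preset correlation of 0.01 and the rotation test fry as alternatives, and adjusted over the lists. Counts of members that passed use the adjustment over all probe sets, and a second count adjusts over the list alone.

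Genes were named by a fixed rule: the 10 largest rises and 10 largest falls among genes with an adjusted p under 0.05 and groups that did not overlap, in each of the first 4 comparisons, and 5 of each in the comparisons with pacing. Where fewer than 3 passed in a direction, the 3 with the smallest p were named as not passing. For the largest rises and falls each sample, Doberman K among them, had to lie beyond the other group. The direction in K was therefore set by the rule for these genes and is no separate check on L and R. Up to 4 members were named of each list described, and a set of muscle genes was named whatever their result. Genes known only by a locus number were counted and not named. Of the genes that the rule names, 2 are not reported here. NPPA, NPPB, MYH6, PLN, STRN, CKM and POSTN were not analysed here, because no tested probe set carried their symbol.

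The alternatives were leaving out each sample, quantile normalization, median centring, pseudocounts of 1 and 64, no filter on signal, a fit of only the compared groups, array weights, the GAPDH 3'/5' ratio as a covariate, the list tests named above and counting genes instead of probe sets. The GAPDH ratio ran from 1.08 to 3.62 in the Dobermans and from 0.967 to 1.09 on the other arrays. As a covariate it therefore goes largely with the Doberman group, and calls lost with it cannot tell degradation from a group difference. Leaving out Dobermans L and R together and filtering at the 70th percentile were added after the data were seen. Overlaps between comparisons were set against 100 simulations of unchanged groups with shared controls. The pipeline was tested on simulated data with 100 probe sets changed by 1 and 100 by 2 on the log2 scale: 28% to 38% of the former and 68% to 91% of the latter passed, and 1.65% to 8.40% of the calls were false. The simulated noise was independent between probe sets and had the same spread in every group. The real groups varied unequally, so these rates need not hold for the real calls. Figures were drawn in Python 3.11.15 with matplotlib 3.10.9.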

Results

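Messenger RNA was measured in heart tissue with a dog microarray, on 13 separately named samples with 1 array each. The samples were 3 control mongrels (P1, P4 and P9), 3 Dobermans with dilated cardiomyopathy (K, L and R), 4 Boxers with dilated cardiomyopathy (1 to 4) and 3 paced mongrels (LV01, LV02 and LV04). Dilated cardiomyopathy is a disease in which the ventricles enlarge and contract poorly, and both breeds are prone to it. Pacing drives the heart through an electrode, and fast pacing is a way of bringing on heart failure in dogs; the labels gave neither its rate nor its length. All control and paced samples came from mongrels and no sample came from a healthy Doberman or Boxer, so breed and disease went together in each comparison of a breed with the controls.

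The median MAS5 signal was 145 ± 2.02 (SD, n = 3) in the controls, 137 ± 5.83 (SD, n = 4) in the Boxers and 213 ± 5.94 (SD, n = 3) in the paced samples. It was 160 in Doberman K, 234 in L and 219 in R. The ratio of the 3' to the 5' GAPDH control probe sets, which rises when RNA is degraded, was 1.08 in Doberman K, 2.10 in L and 3.62 in R, and lay between 0.967 and 1.09 on the other arrays. The same ratio for actin was -2.73 ± 0.42 log2 (SD, n = 3) in the controls, -1.79 ± 0.20 (SD, n = 4) in the Boxers and -2.42 ± 0.19 (SD, n = 3) in the paced samples, and -1.90 in Doberman K, -1.92 in L and -0.08 in R. Every Boxer and every Doberman lay above every control in the actin ratio. For the Boxers the exact permutation p was 0.0286, the smallest possible, and the adjusted p 0.137. The spike-in probe sets, which report RNA added at hybridization, gave 7292 ± 947 (SD, n = 3) in the paced samples, 1582 ± 427 (SD, n = 3) in the controls and 1506 ± 164 (SD, n = 4) in the Boxers. For 3 arrays against 3, the smallest two-sided p that an exact permutation test can give is 0.1, which the differences of paced from control samples in median and spike-in signal both reached. The number of arrays limits the precision of every value given here.

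**Figure D1:**
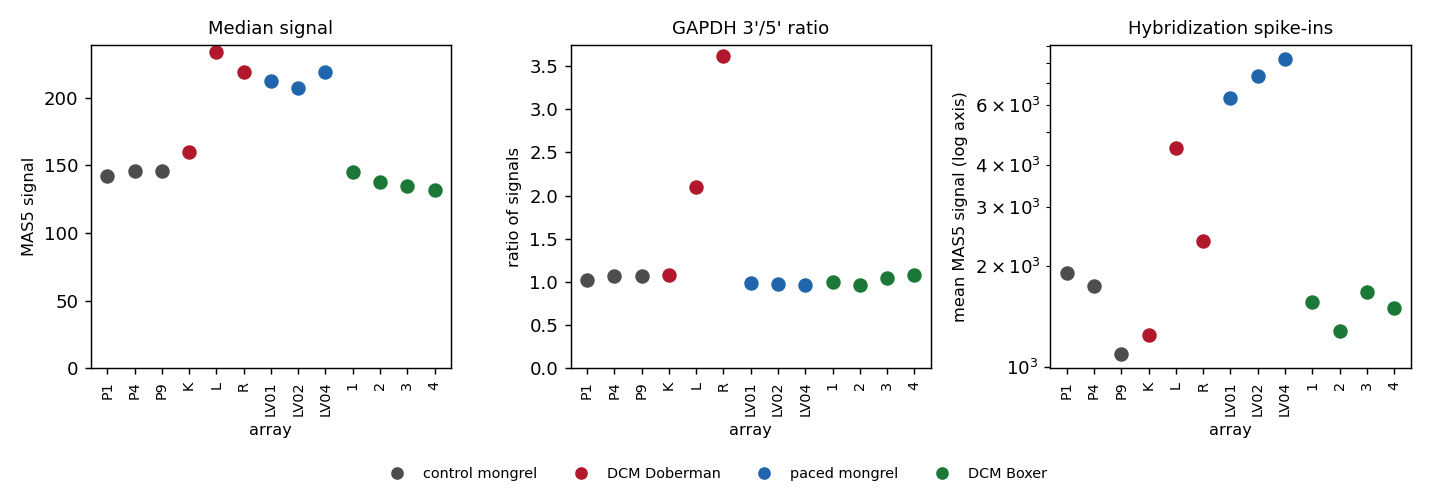
Each point is 1 array, coloured by group: the median MAS5 signal (left), the ratio of the 3' to the 5' GAPDH control probe sets (middle) and the mean signal of the hybridization spike-ins on a log axis (right). Dobermans L and R have GAPDH ratios of 2.10 and 3.62, and the 3 paced arrays have the highest spike-in signals, from 6321 to 8212.

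The first comparison asked which genes differed in the hearts of Dobermans with dilated cardiomyopathy. GJA1, the main gap junction protein of ventricular muscle, was 7.17-fold lower than in the controls, with a signal of 886 ± 419 (SD, n = 3) against 5938 ± 718 (SD, n = 3). CDKN1A, an inhibitor of the cell cycle that responds to stress, was 9.72-fold higher, at 4885 ± 942 (SD, n = 3) against 539 ± 330 (SD, n = 3). PTGR1, a reductase that inactivates prostaglandins and leukotrienes, was 7.37-fold higher, and CLU, a secreted chaperone, was 6.74-fold higher. Many genes for the use of fuel in mitochondria were lower, among them DECR1, a reductase that the oxidation of unsaturated fatty acids needs, at 9.99-fold lower (4.88-fold without R and 19.7-fold without K). Their 3 lists had adjusted p = 0.438 with an estimated correlation, and Dobermans L and R had GAPDH ratios of 2.10 and 3.62.

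Of the 14302 probe sets tested, 3644 passed an adjusted p of 0.05 in limma, 2047 higher and 1597 lower, and 6076 had an unadjusted p under 0.05. The 10 largest rises had log2 changes of 3.59 ± 0.91 (SE) for IGSF1, a membrane protein of the immunoglobulin family, 3.28 ± 0.45 for CDKN1A, 3.19 ± 0.67 for MT2A, a metal-binding metallothionein, and 3.01 ± 0.49 for AQP5, a water channel. IGFBP2, which binds insulin-like growth factors, rose by 2.92 ± 0.59 on the log2 scale, PTGR1 by 2.88 ± 0.28, PKD1, a large membrane receptor, by 2.83 ± 0.61, and CLU by 2.75 ± 0.38. UPP1, which breaks down uridine, and MAP1A, which binds microtubules, rose by 2.69 ± 0.63 and 2.36 ± 0.34. The control signals of AQP5, UPP1, IGSF1 and IGFBP2, from 37.6 to 98.1, lay under the filter level of 108, so the size of these rises depends on the pseudocount. Adjusted p ran from 0.00109 for PTGR1 to 0.0172 for IGSF1. In Doberman K, with a GAPDH ratio of 1.08 and an actin ratio of -1.90 log2, CDKN1A (3.37), MT2A (4.05), PTGR1 (2.71), CLU (2.95) and UPP1 (3.89) also passed with L and R left out. IGSF1 (3.05), AQP5 (2.31), IGFBP2 (3.12), PKD1 (1.62) and MAP1A (1.67) did not pass there. The rule that named these rises required every Doberman to lie above every control, so the direction in K was set by the rule.

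Among the 10 largest falls SUCLA2, a subunit of succinyl-CoA ligase in the citric acid cycle, had a log2 change of -4.62 ± 1.07, and OGDH, the first enzyme of the oxoglutarate dehydrogenase complex, one of -3.64 ± 0.84. PYGM, the muscle enzyme that releases glucose from glycogen, changed by -3.42 ± 0.65, ASB12, part of a ubiquitin ligase, by -3.38 ± 0.45, DECR1 by -3.32 ± 0.66 and LRRC2, a leucine-rich repeat protein, by -3.25 ± 0.65. SELENBP1, which binds selenium, changed by -3.05 ± 0.53, CD36, which takes up fatty acids, by -2.94 ± 0.93, GJA1 by -2.84 ± 0.31 and NDUFA9, a subunit of respiratory complex I, by -2.80 ± 0.68. With L and R left out, PYGM (-1.12), ASB12 (-2.04), DECR1 (-1.36), LRRC2 (-1.27), SELENBP1 (-1.64) and GJA1 (-2.20, adjusted p = 0.00489) still passed. SUCLA2 (-0.69), OGDH (-0.75), CD36 (-0.20) and NDUFA9 (-0.34) then did not. The direction of these falls in K was likewise set by the rule, which required every Doberman to lie below every control.

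Among 23 tested genes of the citric acid cycle and pyruvate entry, 16 fell and 0 rose (18 and 0 adjusted over the list alone), with a median log2 change of -0.86. Beside SUCLA2 and OGDH, the largest falls were those of PDHX and PDHB, parts of the pyruvate dehydrogenase complex, at -2.03 ± 0.41 and -1.83 ± 0.35. Of 29 genes of fatty acid uptake and oxidation, 16 fell and 0 rose (17 and 0 adjusted over the list alone), with a median of -0.77; beside DECR1 and CD36 these included LPL, lipoprotein lipase, at -2.62 ± 0.52, and ACAT1, a mitochondrial thiolase, at -2.07 ± 0.31. Of 52 genes of oxidative phosphorylation, 22 fell and 0 rose (25 and 0 adjusted over the list alone), with a median of -0.48; beside NDUFA9, the complex I subunits NDUFS1, NDUFB5 and NDUFV1 changed by -1.44 ± 0.31, -1.32 ± 0.42 and -1.19 ± 0.31. With a preset correlation of 0.01 the 3 lists had adjusted p of 1.04e-07, 1.48e-05 and 1.04e-07 in camera, and adjusted p = 0.438 with an estimated correlation for each. In Doberman K, 5, 6 and 7 members of these lists passed and the medians were -0.44, -0.50 and -0.46. There PDHB (-0.67) and ACAT1 (-1.19) passed, and LPL (-1.35, adjusted p = 0.239), PDHX, NDUFS1, NDUFB5 and NDUFV1 did not. Over the 104 genes of the 3 lists the median was -0.46 in K, -0.87 in L and -0.49 in R, with GAPDH ratios of 1.08, 2.10 and 3.62.

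Of 15 genes of the intercalated disc, 4 fell and 0 rose: GJA1, CDH2, the cadherin that joins muscle cells (-1.55 ± 0.31), LIMS1, an adaptor at integrin contacts (-1.34 ± 0.30), and ITGB1, an integrin subunit (-1.79 ± 0.59). Over all 5242 genes, 624 rose and 734 fell, so the share called in either direction was near that of this list. CDH2 also passed in Doberman K (-1.84, adjusted p = 0.016), whereas LIMS1 had an adjusted p of 0.207 and ITGB1 was 0.32 above the controls there. DSP, a desmosome protein, had a log2 change of -0.22 ± 0.31 that did not pass. RYR2, the calcium release channel of the sarcoplasmic reticulum, fell to 0.465 of the control level (-1.10 ± 0.21, adjusted p = 0.00746). In K alone it was -0.77 with an adjusted p of 0.124. By the probe set of highest signal its partners did not pass: FKBP1B, which binds the channel, was at 0.69 ± 0.87, TRDN, which anchors it, at 0.05 ± 0.20, and ATP2A2, the calcium pump, at -0.03 ± 0.23. Of their other tested probe sets, 3 of 5 for TRDN fell (-1.49 ± 0.28, -1.30 ± 0.43 and -1.26 ± 0.36), as did 3 of 9 for ATP2A2 (-3.26 ± 0.82, -2.37 ± 0.60 and -0.73 ± 0.24). The 2 larger ATP2A2 falls lay mostly in L (log2 8.64 and 11.41) and R (9.92 and 10.74). In K these probe sets were at 13.56 and 14.23, against control means of 13.97 and 14.50. MYH7, the slow myosin heavy chain, and TTN, the giant spring protein titin, were at 0.47 ± 0.26 and 0.51 ± 0.24 without passing, and 2 of the 5 other MYH7 probe sets passed in the opposite direction, at -2.44 ± 0.55 and -3.06 ± 0.73. These 2 falls also lay mostly in L (log2 10.98 and 9.84) and R (11.36 and 10.78). In K the probe sets were at 14.06 and 14.14, against control means of 14.57 and 14.64. Of the 16 other TTN probe sets, 1 rose (1.04 ± 0.26) and 2 fell (-2.02 ± 0.53 and -0.70 ± 0.24). The one with the larger fall was at log2 12.81 in K, 9.62 in L and 11.85 in R, against a control mean of 13.45. ACTA1, the skeletal muscle actin, was at -0.02 ± 0.37 without passing, and 1 of its 3 other probe sets fell (-3.03 ± 0.32). PDK4, which inhibits pyruvate dehydrogenase, was at -1.46 ± 0.59 without passing.

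Some markers of other cell types and of the matrix rose. Over all 5242 genes, 624 rose and 734 fell. The share of macrophage genes called in either direction, given below, lay near that of all genes. Of 12 smooth muscle and pericyte genes, 5 rose and 1 fell; CRIP1, a LIM protein, rose by 1.96 ± 0.31, SYNPO2, an actin-binding protein, by 1.20 ± 0.29 and MCAM, an adhesion molecule of vessel walls, by 1.19 ± 0.28, and EDNRA, the endothelin receptor, changed by -1.35 ± 0.44. Of 36 genes of the extracellular matrix, 7 rose and 0 fell (6 and 0 adjusted over the list alone); LOXL2, which cross-links collagen, rose by 1.87 ± 0.33, CILP by 1.85 ± 0.47, TIMP2, an inhibitor of matrix proteases, by 1.13 ± 0.30 and THBS1, thrombospondin, by 1.01 ± 0.30. COL1A1 and COL3A1, the fibrillar collagens, were at 0.91 ± 0.62 and -1.03 ± 0.71 without passing. Of 16 macrophage and monocyte genes, 3 rose and 1 fell; these were FCGR1A, a receptor for immunoglobulin G (2.11 ± 0.44), CCL2, a chemokine (1.84 ± 0.41), TYROBP, a signalling adaptor (1.09 ± 0.28), and LYZ, lysozyme (-1.20 ± 0.38). Among 7 cardiac stress genes UCHL1, a deubiquitinase, and HSPB7, a small heat shock protein, rose by 2.16 ± 0.39 and 0.82 ± 0.22, while ANKRD1 and CRYAB were at 0.83 ± 0.32 and 0.72 ± 0.29 without passing. The macrophage and cardiac stress lists had adjusted p of 0.038 each with the preset correlation, and adjusted p = 0.653 and 0.438 with an estimated correlation. CRIP1, SYNPO2, CCL2, THBS1 and UCHL1 passed in Doberman K too, and MCAM (0.80), EDNRA (-0.12), LOXL2 (1.77), CILP (1.97), TIMP2 (1.25), FCGR1A (2.38), TYROBP (1.15), LYZ (-0.42) and HSPB7 (0.27) did not. Of 6 interferon response genes, IRF9, a transcription factor, rose by 0.59 ± 0.16, and MX1, MX2 and OAS2, antiviral proteins, were at 1.62 ± 0.72, 1.45 ± 0.54 and 1.18 ± 0.53 without passing over the 3 Dobermans.

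With an estimated correlation, 0 of 28 lists passed in camera and 2 had an unadjusted p under 0.05; 6 passed with the preset correlation and 10 in the rotation test fry. Without Dobermans L and R, an alternative added after the data were seen, 376 probe sets passed (136 higher and 240 lower, 254 of them in the same direction as before) and 20 of the 46 named calls remained. The count was 1414 without control P1, 1577 without P4, 1836 without P9, 7349 without Doberman K, 1192 without L and 1728 without R. Among the named calls, CD36, EDNRA and ITGB1 were lost in 5 of these 6 fits, HSPB7, LYZ and NDUFB5 in 4, and CILP, IGSF1, IRF9, THBS1, TIMP2 and TYROBP in 3. NDUFA9 and NDUFV1 were lost in 2 and MCAM and SUCLA2 in 1, and CD36, ITGB1 and NDUFB5 also after quantile normalization. Probe sets that passed numbered 95 with the GAPDH ratio as a covariate and 20 in a fit of these 6 arrays alone. The ratio varied mainly among the Dobermans, so a call lost with the covariate cannot tell degradation from a group difference. Of the 46 named calls, 37 were lost with the covariate and 41 in the fit of 6 arrays, where CDKN1A, MT2A, PTGR1, CLU and GJA1 kept theirs; of these only MT2A was lost with the covariate. The median change of all probe sets was 0.19 log2 as deposited and 0.02 after quantile normalization, where 1075 were higher and 1649 lower, and 507 and 3115 after median centring.

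The second comparison asked the same of the Boxers. CIAO2B, which serves the assembly of iron-sulfur proteins, fell to 0.277 of the control level, with a signal of 215 ± 53.7 (SD, n = 4) against 833 ± 295 (SD, n = 3). CMTM6, a membrane protein that stabilises an immune checkpoint ligand, rose 2.72-fold, to 848 ± 212 (SD, n = 4) from 299 ± 61.5 (SD, n = 3). A probe set of ACTA1, the skeletal muscle actin, had the smallest adjusted p, 2.08e-05, with a log2 change of -4.16 ± 0.30, and was chosen for mention after its values were seen. Lists of the extracellular matrix, fibroblasts and macrophages passed as higher with a preset correlation, but had adjusted p = 0.391, 0.482 and 0.541 with an estimated correlation, and no member passed over all probe sets with all samples in the fit.

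In all, 6 of 14302 probe sets passed, 2 higher and 4 lower, and 1058 had an unadjusted p under 0.05 in limma. The log2 change was 1.44 ± 0.23 for CMTM6 (adjusted p = 0.0424) and -1.85 ± 0.25 for CIAO2B (adjusted p = 0.0118). The call of CMTM6 was lost without control P1 (adjusted p = 0.292), P4 (0.173), Boxer 1 (0.155), Boxer 3 (0.126) or Boxer 4 (0.0797) and after quantile normalization (0.0817), and that of CIAO2B without P1 (0.0781). The other 3 were a probe set without a gene symbol at 4.28 ± 0.51, another at -2.17 ± 0.24 and a gene known only by a locus number at -2.87 ± 0.31. The remaining 3 tested probe sets of ACTA1 did not pass and stood at 0.63 ± 0.35, 0.63 ± 0.31 and -0.42 ± 0.28. Below the threshold came IGFBP2 (2.62 ± 0.56, adjusted p = 0.228), S100A4, a calcium-binding protein of fibroblasts and leukocytes (2.02 ± 0.38, adjusted p = 0.118), and PPP3CC, a calcineurin subunit (1.00 ± 0.21, adjusted p = 0.228). PAM16, of the mitochondrial import motor, DENND5B, a regulator of membrane traffic, and WDR82, of a histone methylation complex, stood at -0.77 ± 0.18, -0.84 ± 0.19 and -0.99 ± 0.23, with adjusted p of 0.284, 0.291 and 0.284.

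The 36 matrix genes had a median log2 change of 0.39, an adjusted p of 1.86e-06 with the preset correlation and adjusted p = 0.391 with an estimated correlation. SPP1, osteopontin, stood at 2.66 ± 0.73, CILP at 1.69 ± 0.44, COL12A1, a collagen that links fibrils, at 0.90 ± 0.21 and THBS1 at 0.82 ± 0.28, and adjusted over the list alone 3 members rose. The 10 fibroblast genes had a median of 0.54 (adjusted p = 0.00158 preset and 0.482 with an estimated correlation), with S100A4, MFAP4 at 1.27 ± 0.31, PDGFRL at 0.88 ± 0.52 and FBLN2 at 0.66 ± 0.28. The 16 macrophage genes had a median of 0.56 (adjusted p = 0.000104 preset and 0.541 with an estimated correlation), with FCGR1A at 1.37 ± 0.41, CCL2 at 1.26 ± 0.38, LYZ at 1.01 ± 0.35 and TYROBP at 0.48 ± 0.27; adjusted over the list alone, 2 fibroblast and 2 macrophage genes rose. The 9 atrial and conduction genes had a median of 0.39 (adjusted p = 0.0222 preset, 0.00839 in fry and 0.391 with an estimated correlation), and adjusted over the list alone 3 rose and 1 fell. They included DKK3 at 1.56 ± 0.39, NR2F1 at 1.15 ± 0.25, NR2F2 at 0.91 ± 0.24, the latter pair transcription factors of atrial identity, and PAM, a peptide-amidating enzyme of atrial granules, at -0.40 ± 0.15.

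Lists of the working muscle cell lay slightly lower. Oxidative phosphorylation had a median of -0.18 (adjusted p = 0.00481 preset and 0.688 with an estimated correlation), with UQCR11, UQCRC1, UQCR10 and NDUFS7 between -0.48 and -0.28. Fatty acid uptake and oxidation had a median of -0.23 (adjusted p = 0.0129 preset and 0.566 with an estimated correlation), with PDK4, the kinase, at -1.34 ± 0.55, LPL at -1.12 ± 0.49, BDH1 at -0.64 ± 0.31 and MLYCD at -0.31 ± 0.16. The sarcomere and Z-disc list had a median of -0.19 (adjusted p = 0.0416 preset and 0.7 with an estimated correlation), with NEBL at -0.90 ± 0.35, MYOM2 at -0.86 ± 0.27, FLNC at -0.66 ± 0.32 and TMOD1 at -0.42 ± 0.17. After quantile normalization the sarcomere call was lost (adjusted p = 0.73) and the other 2 remained. GJA1 was at -0.84 ± 0.29 (adjusted p = 0.53), RYR2 at -0.22 ± 0.20, TRDN at -0.09 ± 0.19, ATP2A2 at -0.23 ± 0.22, MYH7 at -0.29 ± 0.25, COL1A1 at 0.87 ± 0.58 and COL3A1 at 0.50 ± 0.67. DSP and TTN, at -0.08 ± 0.29 and -0.08 ± 0.23, were at 0.03 and 0.17 after quantile normalization. FKBP1B had a log2 signal between 7.15 and 7.61 in all 4 Boxers, against 11.07, 11.55 and 7.09 in controls P1, P4 and P9, and did not pass (-2.53 ± 0.81, adjusted p = 0.457); without P9 its change was -3.94 and its adjusted p 0.0053.

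With an estimated correlation 0 of 28 lists passed in camera, 2 at an unadjusted p under 0.05; 7 passed with the preset correlation and 1 in fry. The count of probe sets was 118 without Dobermans L and R, which share the variance estimate of the fit, 254 with array weights, 25 in a fit of these 7 arrays alone and 12 without control P9. GJA1 (adjusted p = 0.048), S100A4 (0.0437), PPP3CC (0.0394), PAM16 (0.0368) and WDR82 (0.00473) passed when L and R were left out. So did CILP (0.0437) and COL12A1 (0.0455) of the matrix, MFAP4 (0.0455) of fibroblasts and NR2F1 (0.0446) of the atrial list.

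The next comparison asked what pacing changed in mongrel hearts. ACTA1, the skeletal muscle actin that the fetal and the stressed heart express, was 7.38-fold higher, at 5705 ± 561 (SD, n = 3) against 775 ± 216 (SD, n = 3). GJA1 was 5.16-fold lower, at 1149 ± 232 (SD, n = 3) against 5938 ± 718 (SD, n = 3). SPP1, osteopontin, was 5.96-fold higher (3.37-fold without control P4 and 8.96-fold without P9) and TEK, the angiopoietin receptor of endothelium, was 2.18-fold lower. All 3 paced arrays had higher spike-in and median signals than every control, so these differences between the arrays and pacing went together.

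Of 14302 probe sets, 1747 passed, 1212 higher and 535 lower, and 4100 had an unadjusted p under 0.05. The largest rises reported here were those of LAMTOR4, part of the lysosomal Ragulator complex (2.97 ± 0.39), ACTA1 (2.88 ± 0.37), SLAMF1, a receptor of leukocytes (2.72 ± 0.51), SPP1 (2.58 ± 0.79) and ATP2B2, a calcium pump of the plasma membrane (2.57 ± 0.72). TRIM17, a ubiquitin ligase, TRMT1, a transfer RNA methyltransferase, DEFB4A, a defensin, and ICA1, an islet cell autoantigen, rose by 2.57 ± 0.38, 2.48 ± 0.38, 2.45 ± 0.57 and 2.44 ± 0.42. Except for ACTA1 and SPP1, the control signals of these genes lay between 44.8 and 92.9, under the filter level of 108, so the size and order of their changes depend on the pseudocount. A second ACTA1 probe set rose by 3.31 ± 0.33, another was at -0.21 ± 0.30, and the one that was low in the Boxers changed by -1.26 ± 0.32. The call of SPP1 was lost without P1 (adjusted p = 0.0853), P4 (0.188), LV01 (0.111), LV02 (0.149) or LV04 (0.0698).

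The largest falls were those of UBXN1, a ubiquitin-binding cofactor (-3.00 ± 0.37), NUP133, a nuclear pore protein (-2.93 ± 0.32), CD3E, of the T cell receptor complex (-2.89 ± 0.30), ANKFY1, an endosomal protein (-2.73 ± 0.57), and ENTPD5, a nucleotidase (-2.63 ± 0.49). MTIF3, a mitochondrial initiation factor, MYCT1, a gene of endothelium, CHKA, choline kinase, SHC2, a signalling adaptor, and CLPB, a mitochondrial chaperone, changed by -2.59 ± 0.51, -2.59 ± 0.56, -2.51 ± 0.31, -2.44 ± 0.48 and -2.44 ± 0.33. Except for UBXN1 and CLPB, the paced signals of these 10 genes lay between 20.7 and 87.5, so the size and order of their falls depend on the pseudocount too. GJA1 changed by -2.37 ± 0.31 (adjusted p = 0.00116). RYR2, at -0.69 ± 0.21, had an adjusted p of 0.05 that did not pass, and passed without Dobermans L and R (0.0124). By the probe set of highest signal the other genes named in advance did not pass, at -0.40 ± 0.26 for MYH7, -0.45 ± 0.23 for ATP2A2, -0.33 ± 0.24 for TTN, -0.44 ± 0.31 for DSP, -0.25 ± 0.59 for PDK4, -0.09 ± 0.87 for FKBP1B, -0.05 ± 0.20 for TRDN, 0.74 ± 0.62 for COL1A1 and 0.05 ± 0.71 for COL3A1. Of the 16 other TTN probe sets, 2 rose (1.62 ± 0.50 and 1.00 ± 0.26) and 1 fell (-1.14 ± 0.24). TTN, PDK4 and TRDN were at 0.06, 0.02 and 0.20 after quantile normalization.

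Of 52 oxidative phosphorylation genes 4 fell and 0 rose (1 and 0 adjusted over the list alone): COX15, which makes the heme of cytochrome oxidase (-1.11 ± 0.34), NDUFA2 of complex I (-0.69 ± 0.19), CYC1 of complex III (-0.69 ± 0.21) and COX8A, a subunit of cytochrome oxidase (-0.68 ± 0.15). The list had an adjusted p of 0.000299 with the preset correlation and adjusted p = 0.795 with an estimated correlation, and after quantile normalization its median moved from -0.34 to -0.11 and the preset p to 0.774. Of 14 endothelial genes 2 fell and 0 rose, TEK (-1.12 ± 0.22) and ECSCR, a receptor at endothelial contacts (-2.23 ± 0.58), while AQP1, a water channel, and SELP, P-selectin, were at -0.55 ± 0.19 and 0.68 ± 0.26 without passing. Of 10 lymphocyte genes NKG7, of cytotoxic granules, rose by 2.37 ± 0.39 and CD3E fell, and IL2RG, a cytokine receptor chain, and CCL4, a chemokine, were at 1.67 ± 0.53 and 0.69 ± 0.23 without passing. Of 36 matrix genes SPP1 and LOXL2 (1.25 ± 0.33) rose and 0 fell, and CCN2, a connective tissue growth factor, and TGFB1, transforming growth factor, were at 0.63 ± 0.30 and -0.63 ± 0.23 without passing. These 3 lists had adjusted p = 0.795, 0.886 and 0.795 with an estimated correlation. Over all 5242 genes, 268 rose and 212 fell with pacing.

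With an estimated correlation 0 of 28 lists passed in camera, 0 at an unadjusted p under 0.05; 1 passed with the preset correlation and 0 in fry. The split of the calls turned with the scaling, to 633 higher and 848 lower after quantile normalization and 530 and 3394 after median centring. With only probe sets above the 70th percentile of signal tested, an alternative added after the data were seen, 220 passed, 100 higher and 120 lower. The count was 868 without P1, 822 without P4, 1114 without P9, 811 without LV01, 1017 without LV02 and 816 without LV04, and 4407 without Dobermans L and R. Leaving out 1 of the 6 samples at a time, the calls of ATP2B2, COX15 and CYC1 were lost in all 6 fits, those of ECSCR, NDUFA2 and SPP1 in 5, LOXL2 in 4, DEFB4A in 3 and COX8A in 1. After quantile normalization CYC1 and SPP1 lost theirs.

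**Figure D2:**
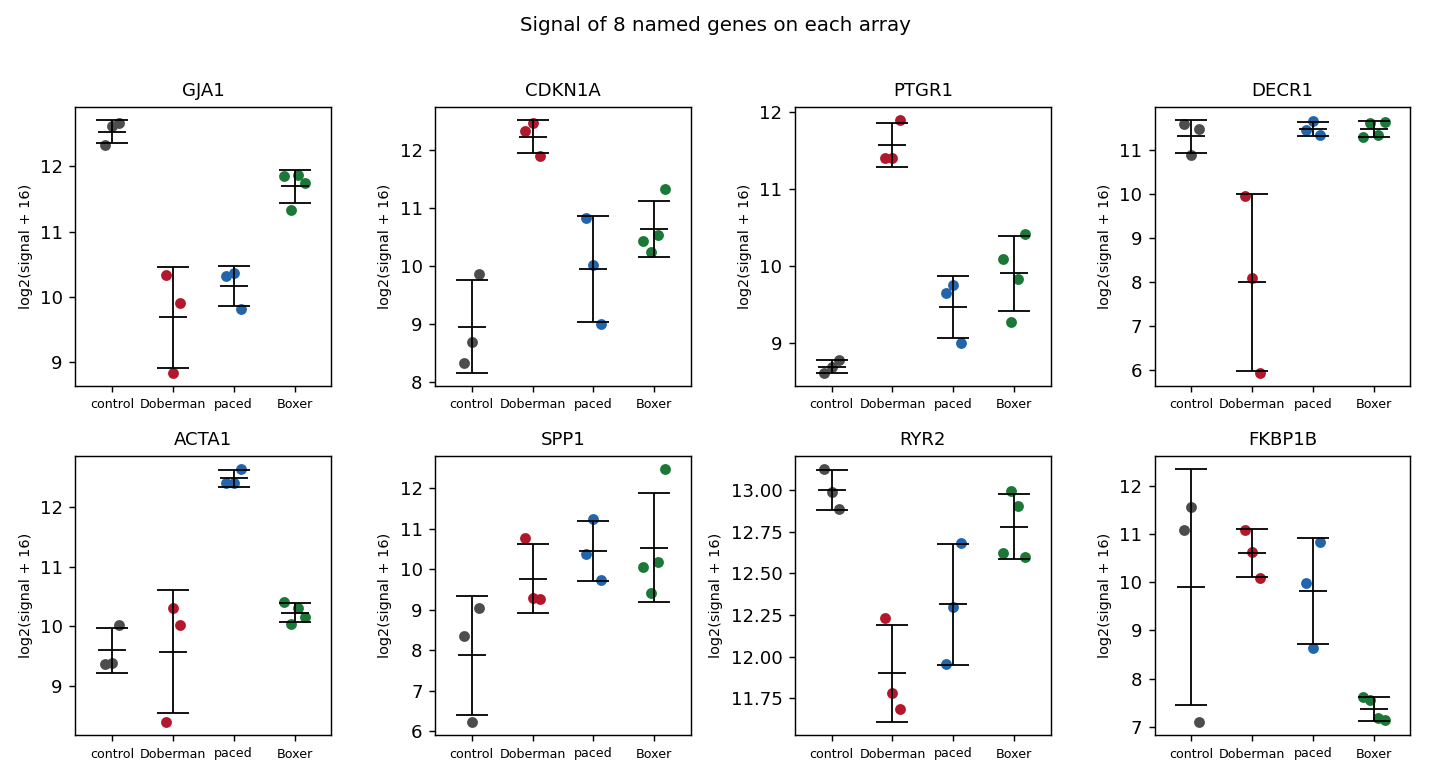
Log2 MAS5 signal plus 16 of 8 named genes on each array (points), with the mean and SD of each group (bars), for 3 control, 3 Doberman, 3 paced and 4 Boxer samples. GJA1 is low in the Doberman and paced samples, and FKBP1B is low in the 4 Boxers and in 1 control, P9 (7.09).

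The fourth comparison set the breeds side by side and tests directly whether the Doberman hearts differed from the Boxer hearts. FKBP1B, which binds the ryanodine receptor, was 9.35-fold higher in the Dobermans, at 1595 ± 537 (SD, n = 3) against 152 ± 28.7 (SD, n = 4). GJA1 was 4.02-fold lower in the Dobermans, at 886 ± 419 (SD, n = 3) against 3339 ± 540 (SD, n = 4). BDNF, a neurotrophin, was 4.51-fold higher, and DECR1, ACAT1 and other genes of mitochondrial fuel use were lower, with adjusted p = 0.745 for their lists with an estimated correlation.

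Of 14302 probe sets, 5066 passed, 3117 higher in the Dobermans and 1949 lower, and 6899 had an unadjusted p under 0.05. The largest rises were those of PKD1 (3.54 ± 0.57), FKBP1B (3.23 ± 0.81, adjusted p = 0.0118), NEFH, a neurofilament (2.18 ± 0.36), BDNF (2.17 ± 0.28), MDC1, of the DNA damage response (2.15 ± 0.30), PBXIP1 (2.03 ± 0.65), TM4SF5 (2.01 ± 0.39), LRRC52 (1.98 ± 0.39), PSD (1.95 ± 0.34) and RITA1 (1.94 ± 0.36). The rule that named the largest rises and falls required every Doberman, K among them, to lie beyond every Boxer. The direction in K was therefore set by the rule. With Doberman K alone BDNF passed (1.58). PKD1 (2.33), FKBP1B (3.70), NEFH (1.63), MDC1 (1.63), PBXIP1 (2.36), TM4SF5 (1.31), LRRC52 (1.28), PSD (1.17) and RITA1 (1.74) did not. The largest falls were those of DECR1 (-3.49 ± 0.62), ASB12 (-3.06 ± 0.42), MAP3K15, a kinase (-2.89 ± 0.48), PYGM (-2.68 ± 0.61), PDIA3, a chaperone of the endoplasmic reticulum (-2.48 ± 0.60), LANCL1, which binds glutathione (-2.44 ± 0.39), HACD3, of fatty acid elongation (-2.37 ± 0.59), PPP3CB, a calcineurin subunit (-2.36 ± 0.57), TMEM260 (-2.34 ± 0.24) and LRRC2 (-2.27 ± 0.61). DECR1 (-1.52), ASB12 (-1.72), MAP3K15 (-1.48), LANCL1 (-1.06) and TMEM260 (-2.42) passed with K alone. The others did not, at -0.38 for PYGM, -0.36 for PDIA3, -0.47 for PPP3CB, -0.28 for LRRC2 and -2.38 for HACD3. For PKD1, NEFH and LRRC52 in the Boxers and ASB12, MAP3K15, HACD3 and TMEM260 in the Dobermans the signal lay between 39.5 and 82.4, so the size of the change depends on the pseudocount. GJA1 changed by -2.01 ± 0.29 (adjusted p = 0.0021; -1.37 and 0.0224 with K alone) and RYR2 by -0.88 ± 0.20 (adjusted p = 0.00819; -0.55 and 0.219 with K alone). MYH7 passed at 0.76 ± 0.25 (adjusted p = 0.0307), but it was at -0.17 after quantile normalization, and of its 5 other tested probe sets 2 were higher (1.09 ± 0.30 and 1.36 ± 0.35) and 2 lower (-1.83 ± 0.51 and -2.18 ± 0.68). ATP2A2 (0.20 ± 0.22), TRDN (0.14 ± 0.19), TTN (0.59 ± 0.23), DSP (-0.14 ± 0.29), PDK4 (-0.12 ± 0.55), COL1A1 (0.04 ± 0.58) and COL3A1 (-1.54 ± 0.67) did not pass by the probe set of highest signal. Other probe sets did, for ATP2A2 2 of 9 lower (-2.86 ± 0.77 and -2.10 ± 0.57) and for TRDN 3 of 5 lower (-1.27 ± 0.34, -1.21 ± 0.26 and -0.51 ± 0.15) and 1 higher (1.07 ± 0.38). In K the 2 ATP2A2 probe sets were at log2 13.56 and 14.23, against Boxer means of 13.57 and 14.23. The 2 lower MYH7 probe sets were at 14.06 and 14.14 in K, against Boxer means of 13.97 and 13.77. For TTN 2 of 16 were higher (1.15 ± 0.25 and 1.07 ± 0.38) and 1 lower (-2.17 ± 0.49).

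Of the 23 citric acid cycle genes 16 were lower and 0 higher, with a median of -0.98; SUCLA2, OGDH, IDH1, the cytosolic isocitrate dehydrogenase, and PDHX changed by -4.13 ± 1.00, -2.45 ± 0.78, -1.90 ± 0.47 and -1.70 ± 0.38. Of 29 fatty acid genes 12 were lower and 1 higher, with CD36 at -2.36 ± 0.87, ACAT1 at -2.06 ± 0.29 and LPL at -1.50 ± 0.49 after DECR1. Of 52 oxidative phosphorylation genes 19 were lower and 0 higher, with NDUFA9 at -2.47 ± 0.64, NDUFB5 at -1.35 ± 0.39, NDUFB3 at -1.18 ± 0.35 and NDUFS1 at -1.17 ± 0.29. Of 30 proteasome genes 10 were lower and 3 higher, with PSMA6 at -1.82 ± 0.40, PSMA2 at -1.27 ± 0.28, PSMC5 at -1.09 ± 0.25 and PSMD10 at -1.04 ± 0.30. Over all 5242 genes, 881 were higher and 909 lower in the Dobermans. The 4 lists had adjusted p of 1.15e-05, 0.00355, 0.000269 and 0.0442 with the preset correlation, and adjusted p = 0.745 with an estimated correlation for each. In Doberman K, 1, 3, 5 and 0 of the members were lower, ACAT1 among them (-1.18), and OGDH and CD36 stood at 0.44 and 0.38 above the Boxers.

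With an estimated correlation 0 of 28 lists passed in camera, 0 at an unadjusted p under 0.05; 4 passed with the preset correlation and 6 in fry. Without Dobermans L and R 304 probe sets passed, 128 higher and 176 lower, and 8 of the 38 named calls remained; with the GAPDH ratio as a covariate 56 passed and 37 of the 38 named calls were lost, all but that of TMEM260. Since the GAPDH ratio varied mainly among the Dobermans, calls lost with the covariate cannot tell degradation from a difference between the breeds. In a fit of these 7 arrays alone 2114 passed and 12 of the 38 were lost. The count was 8110 without K, 2213 without L, 2754 without R and 3299 without Boxer 3. Leaving out 1 of the 7 samples at a time, the calls of CD36 and MYH7 were lost in 6 fits, LPL and OGDH in 5, PBXIP1 in 3, IDH1, NDUFA9 and SUCLA2 in 2 and PSMD10 in 1. CD36 and PBXIP1 also lost theirs after quantile normalization. After quantile normalization 1550 were higher and 2124 lower, and the median change of all probe sets moved from 0.20 to 0.00.

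Calls shared between comparisons were counted by direction. The Doberman and pacing comparisons shared 387 probe sets that were higher in both and 108 that were lower in both, where independent lists would share 173 and 59.7, and 46 and 9 went opposite ways. After quantile normalization they shared 213, 90 higher and 123 lower. GJA1 was among those lower in both. All comparisons with control use the same 3 controls, which alone makes the changes alike across genes. The covariance of the Doberman and pacing changes across probe sets, which are not independent replicates, was 0.216. Unchanged groups set against shared controls gave 0.0454 on average and at most 0.05 in 100 simulations, and r was 0.375 against a simulated 0.328. Every Doberman and every paced array also had a higher median signal than every control. These covariances were taken on the values as deposited, so they cannot separate shared changes of expression from this shared difference between arrays. For the Boxers the covariance was 0.0805 with the Dobermans and 0.0704 with pacing, but r was 0.26 and 0.263, below the simulated 0.368 and 0.563. Dobermans and Boxers shared 4 of the 6 Boxer calls in the same direction, 2 higher and 2 lower, where independent lists would share 0.286 and 0.447.

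The 2 remaining comparisons set each breed against the paced mongrels, where breed, disease and the spike-in signal of the arrays all differ. In the Dobermans MAP1A was higher than after pacing, at 847 ± 306 (SD, n = 3) against 20.8 ± 2.87 (SD, n = 3), as was CD3E. Their paced signals, 20.8 and 34.6, lay under the filter level of 108, so their folds depend on the pseudocount. With the pseudocount of 16 their log2 changes were 4.48 ± 0.34 and 4.19 ± 0.30. ACTA1 was 7.5-fold lower (4.99-fold without K), at 862 ± 482 (SD, n = 3) against 5705 ± 561 (SD, n = 3). Other ACTA1 probe sets had mean log2 values of 9.54 and 8.46 in the Dobermans, against 12.72 and 10.23 after pacing. A further one went the opposite way, at 10.47 against 9.44. DECR1 was 11.3-fold lower (5.5-fold without R and 22.2-fold without K). In the Boxers GJA1 was 2.89-fold higher than after pacing, with a log2 change of 1.53 ± 0.29 and an adjusted p of 0.00414, and it did not differ past the threshold between Dobermans and paced mongrels (-0.47 ± 0.31, adjusted p = 0.279). RYR2, FKBP1B, ATP2A2, TRDN, DSP, PDK4, COL1A1 and COL3A1 passed in neither of these comparisons by the probe set of highest signal. Other probe sets of these genes did not all lie close. A RYR2 probe set had a mean log2 value of 8.06 in the Dobermans and 9.64 after pacing. A TRDN probe set was at 7.20 and 9.39, and another TRDN probe set went the opposite way, at 9.28 and 8.60.

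In the Dobermans 3514 probe sets passed, 1863 higher and 1651 lower. Other large rises were those of CYP4A11, a fatty acid hydroxylase (3.38 ± 0.36), and C2, a complement protein (3.21 ± 0.40), with paced signals of 47.1 and 33.3, and the next largest falls those of DCHS1, a cadherin (-3.11 ± 0.60), PYGM (-3.05 ± 0.65) and LPL (-2.96 ± 0.52, lost with K alone, adjusted p = 0.0671). Of 12 smooth muscle and pericyte genes 6 were higher and 0 lower, with MCAM at 3.11 ± 0.28, CRIP1 at 1.57 ± 0.31, SYNPO2 at 1.48 ± 0.29 and MYL9, a myosin light chain, at 1.22 ± 0.27; CRIP1 and MYL9 were lost with K alone (adjusted p = 0.0773 and 0.121). Over all 5242 genes, 708 were higher and 579 lower than after pacing. The list had an adjusted p of 0.0457 with the preset correlation and adjusted p = 0.809 with an estimated correlation. MYH7 (0.87 ± 0.26) and TTN (0.84 ± 0.24) passed, but were at -0.23 and -0.01 after quantile normalization, and 2 of the other probe sets of each passed in the opposite direction. The count was 6183 without Doberman K, 2156 without LV01, 2138 without LV02 and 2149 without LV04. It was 1028 with the GAPDH ratio as a covariate and 524 in a fit of these 6 arrays alone. Of the 14 calls among the largest changes and the list members, 5 and 6 were lost in the latter pair of fits. MYH7 and TTN are not among the 14. For lists, 0 of 28 passed in camera with an estimated correlation and 1 had an unadjusted p under 0.05, while 5 passed with the preset correlation and 7 in fry.

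In the Boxers 2536 probe sets passed against pacing, 694 higher and 1842 lower, and after quantile normalization 1123 were higher and 809 lower. MTIF3 (2.86 ± 0.47), ENTPD5 (2.80 ± 0.46), MAP1A (2.73 ± 0.32), CD3E (2.69 ± 0.28) and NUP133 (2.64 ± 0.30) had the largest rises. Their paced signals, from 20.8 to 87.5, lay under the filter level of 108, so the size and order of these rises depend on the pseudocount. ATP2B2 (-3.25 ± 0.67), AZIN2, an antizyme inhibitor (-2.69 ± 0.48), LAMTOR4 (-2.63 ± 0.37), NKG7 (-2.61 ± 0.36) and RAB28 (-2.35 ± 0.68) had the largest falls, of which the first 4 had Boxer signals of 43.8 to 101. The call of RAB28 was lost without LV01 (adjusted p = 0.0813), LV02 (0.0885), LV04 (0.0832), Boxer 1 (0.082) or Boxer 3 (0.0846). Of 12 smooth muscle and pericyte genes MCAM (1.74 ± 0.26), SYNPO2 (1.03 ± 0.27) and ACTA2, smooth muscle actin (0.95 ± 0.26), were higher and SMTN, smoothelin, was lower (-1.14 ± 0.26). Over all 5242 genes, 306 were higher and 435 lower than after pacing. The list had adjusted p of 0.0873 with the preset correlation, 0.873 with an estimated correlation and 0.0297 in fry. The count was 1320 without LV01, 1590 without LV02, 1287 without LV04, 1633 without Boxer 3 and 5126 without Dobermans L and R. With 1 of the 7 samples left out, the call of ACTA2 was lost in 5 fits and that of SYNPO2 in 3, and after quantile normalization that of RAB28. For lists, 0 of 28 passed in camera with an estimated correlation and 1 had an unadjusted p under 0.05, while 0 passed with the preset correlation and 3 in fry.

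**Figure D3:**
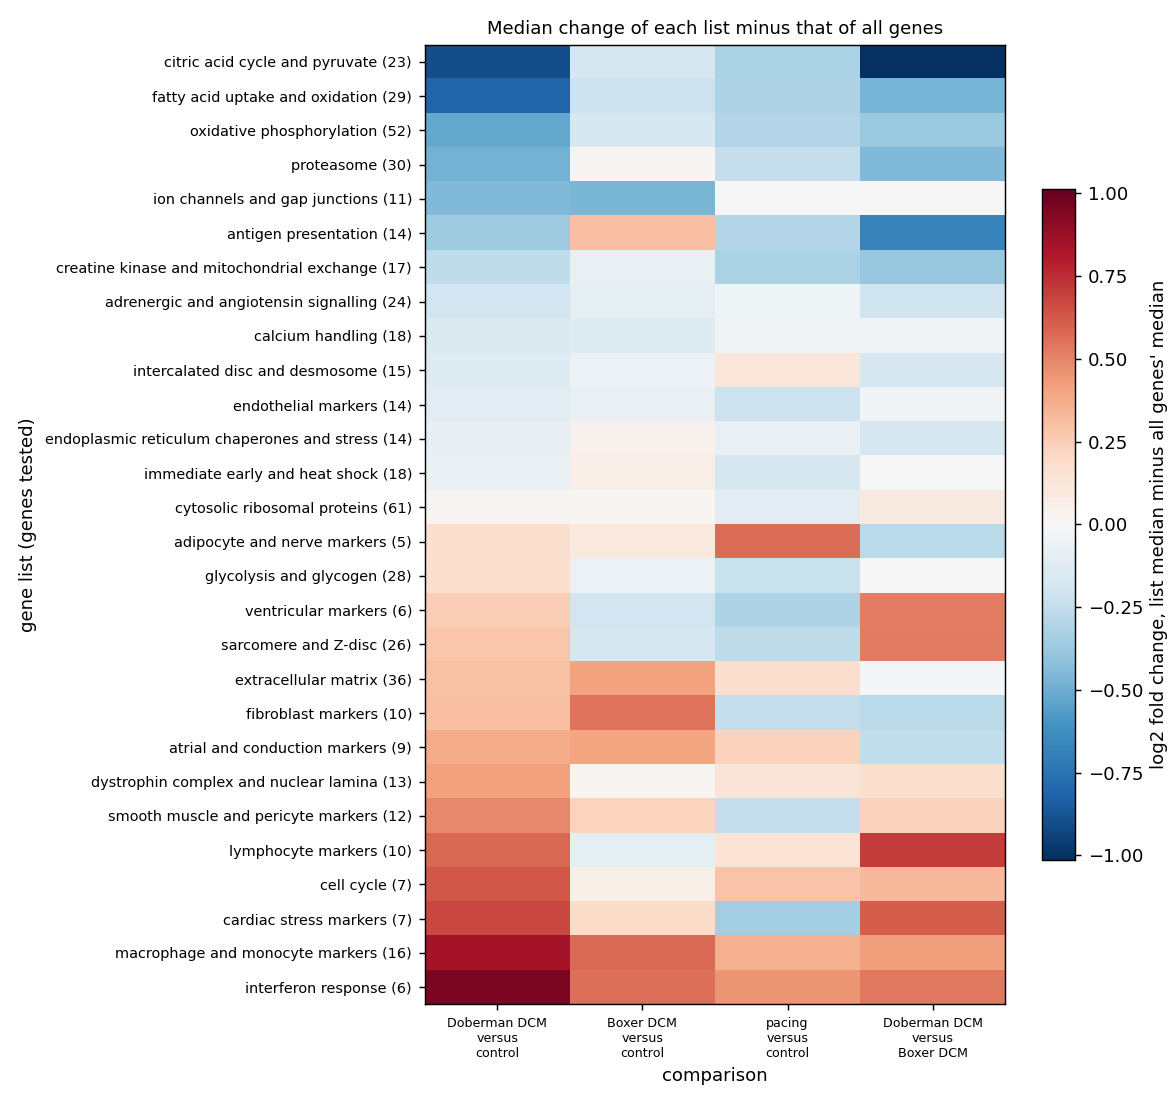
Median log2 fold change of each of 28 gene lists minus the median of all genes, in 4 comparisons, ordered by the Doberman values; red is higher and blue lower. The citric acid cycle, fatty acid and oxidative phosphorylation lists stand at the low end in the Dobermans, where Dobermans L and R have GAPDH ratios of 2.10 and 3.62.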

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

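The splits of the samples and the first test of control P9 below were set before their results were seen; the other tests of the 3 patterns, on energy metabolism, on the direction of the pacing calls and on FKBP1B, were chosen only after the result was seen.

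A sample far from the others was looked for among the 4 Boxers in 96 values, those of named genes and of the array measures, and chance marks about 1 in 20. In 6 genes the gap of 1 Boxer to the nearest other, as a share of the range of the Boxers, was above the critical value of Dixon's test at 95%. These were MYOM2 (0.886; 13.05 in Boxer 2 and 12.42 to 12.49 in the others, log2), PPP3CB (0.907; 10.01 in Boxer 4 and 10.41 to 10.46), PSD (0.889; 8.30 in Boxer 2 and 7.50 to 7.59), PSMA6 (0.833; 11.12 in Boxer 1 and 11.26 to 11.29), RITA1 (0.861; 11.70 in Boxer 1 and 10.59 to 10.75) and SMTN (0.847; 12.44 in Boxer 2 and 11.45 to 11.60).

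The difference between the breeds was tested directly for 19 genes named against the controls in both, and 6 passed: FKBP1B (log2 3.23), GJA1 (-2.01), LPL (-1.50), LYZ (-2.21), MYH7 (0.76, but -0.17 after quantile normalization) and RYR2 (-0.88). With L and R left out, the change was 3.70 for FKBP1B, -0.23 for LPL, 0.05 for MYH7 and -0.55 for RYR2. Leaving out 1 sample at a time, the call of LPL was lost in 5 of 7 fits and that of MYH7 in 6. With the GAPDH ratio, which varied mainly among the Dobermans, as a covariate, 37 of the 38 named calls between the breeds were lost. In the main fit 5066 of all probe sets passed between the breeds. Signal outside the tested probe sets stood apart in the spike-ins, where the lowest paced array was at 6321 and the highest of all other arrays was at 4479.

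For each comparison the split of the samples into the real groups was set against the other splits of the same sizes. For the Boxers against controls 1 of 35 splits, the real one, gave as many probe sets (6, with 1 as the highest other). It was 1 of 35 for the breeds (5066 and 4) and for the Boxers against pacing (2536 and 0). This is the smallest share that 35 splits can give, without adjustment over the comparisons. It argues against a chance split without excluding it. The splits cannot tell disease, breed or pacing apart from array measures that differ between the groups. With 3 samples against 3 the splits are too few for a share under 0.05: 1 of 10 reached the real count for the Dobermans (3644, highest other 7), for pacing (1747 and 0) and for the Dobermans against pacing (3514 and 4).

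The lower energy metabolism genes in the Dobermans, 104 genes of 3 lists, had a median against the controls of -0.46 in K, -0.87 in L and -0.49 in R; each control set against the other 2 lay between -0.23 and 0.14, the paced arrays between -0.46 and -0.29 and the Boxers between -0.24 and -0.14. The median of the Dobermans minus that of all genes was -0.66 as deposited and -0.51 after quantile normalization. A factor common to a whole array drops out of this gap, so the gap bears only on other differences in scale between arrays. It argues against those as the whole cause, though it shrank. RNA degradation cannot be told apart from a true fall: K had a GAPDH ratio of 1.08, like the controls, but an actin ratio (-1.90 log2) above theirs (at most -2.34), while R, with the highest GAPDH ratio, stood at -0.022 against K, and 1543 pairs of probe sets of the same gene differed by a median of 0.91 in L, 0.83 in R and 0.29 in K, but also by 0.44 to 0.46 on the paced arrays. A lower share of heart muscle cells as the whole cause would lower sarcomere genes alike and stays open too. The median of the sarcomere genes lay above that of the energy genes by 0.27 in K, 1.48 in L and 1.17 in R. The highest control was at 0.08. After quantile normalization these gaps were 0.31, 0.47 and 0.48, against at most 0.03 in a control and 0.25 in paced LV01. With all probe sets of these genes the gap was only 0.17 in K, against at most 0.12 in a control. Disease and breed stay open and were not tested apart.

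The excess of higher over lower probe sets after pacing, 69.4% of the calls, was weighed next. After quantile normalization 42.7% of the calls were higher, and with the filter at the 70th percentile 45.5%, so scaling and raised values of low-signal probe sets are candidate explanations of the excess. The labels give no batch, but the paced arrays stood apart in spike-in signal, with the lowest at 6321 and the highest other array, Doberman L, at 4479, so a batch of arrays and pacing cannot be told apart for this pattern. Which of the calls pacing itself brought about stays open.

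FKBP1B was low in all 4 Boxers and in control P9, and high in Dobermans L and R. Poor RNA was argued against by the GAPDH ratios of P9 and the Boxers, of which the highest was 1.09, and by the Dobermans, which had FKBP1B at 10.08 to 11.08 with actin ratios of -1.92 to -0.08 log2, against -1.97 to -1.56 in the Boxers. That P9 is a mislabelled Boxer was tested on correlations, and the value set beforehand was narrowly met. The mean r of P9 was 0.955 with the Boxers (SD 0.00480, highest 0.958) and 0.954 with P1 and P4. By sample, r was 0.958, 0.957, 0.958 and 0.948 with Boxers 1 to 4, and 0.954 and 0.953 with P1 and P4. A second test argues against it: of 12 probe sets that passed without P9, P9 lay nearer the Boxers in 4 and nearer P1 and P4 in 8, among them the ACTA1 probe set that is low in the Boxers. A variant in the sequence under the single FKBP1B probe set, and a true difference, stay open and were not tested.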

How the results depend on the processing

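Leaving out Dobermans L and R and the filter at the 70th percentile were tests chosen only after the result was seen. Samples were not paired, since the labels name no animal in more than 1 sample. Of the named genes past the threshold, 4 of 46 kept their call and direction under each alternative set before the data were seen for the Dobermans, 0 of 2 for the Boxers and 20 of 29 for pacing. Such calls numbered 1 of 38 between the breeds, 7 of 14 for the Dobermans against pacing and 10 of 14 for the Boxers against pacing. For the comparisons of a breed with pacing this tally covers only the largest changes and the list members. It leaves out MYH7 and TTN, which passed for the Dobermans, and GJA1, which passed for the Boxers. Probe sets with a signal near background limit the precision, and 14302 of 23836 passed the filter. Leaving out 1 sample at a time, the count ranged over 1192 to 7349 (Doberman; L and K), 5 to 12 (Boxer; Boxer 3 and P9), 811 to 1114 (pacing; LV01 and P9), 2213 to 8110 (between breeds; L and K), 2138 to 6183 (Doberman against pacing; LV02 and K) and 1287 to 1862 (Boxer against pacing; LV04 and Boxer 1). No list passed in camera with an estimated correlation (0 to 0) in any of these fits, against 2, 2, 0, 0, 1 and 1 at an unadjusted p under 0.05 with all samples. For the Dobermans, log2 values that turned sign ranged over ATP2A2 -0.31 to 0.14, FKBP1B -0.71 (without P9) to 1.52, TRDN -0.18 to 0.27 and DSP -0.61 to 0.25. For pacing they were FKBP1B -1.49 to 0.74, TRDN -0.10 to 0.0078, COL3A1 -0.36 to 0.49 and the lymphocyte list median -0.043 to 0.15. Between breeds they were COL1A1 -0.39 to 0.50, ATP2A2 -0.085 to 0.36, PDK4 -0.53 to 0.68, TRDN -0.089 to 0.37 and DSP -0.53 to 0.33. None of these passed with all samples in that comparison. Quantile normalization left 213 calls shared between Dobermans and pacing and 1 between Boxers and pacing. It turned MYH7 to -0.25 (Doberman), DSP to 0.026 and TTN to 0.17 (Boxer). For pacing it turned TRDN to 0.20, PDK4 to 0.015, TTN to 0.064 and the lymphocyte list median to -0.091. Between breeds it turned MYH7 to -0.17, TTN to -0.12, ATP2A2 to -0.16 and PDK4 to 0.040. Median centring gave 3924 (pacing) and 5403 (Boxer against pacing) probe sets. It turned TRDN to -0.39 (Doberman), COL3A1 to -0.46 (pacing), and ATP2A2 to -0.31, TRDN to -0.37 and COL1A1 to -0.47 (between breeds). Fitting only the compared groups gave 20 (Doberman), 25 (Boxer), 3576 (pacing), 2114 (between breeds), 524 (Doberman against pacing) and 5197 (Boxer against pacing). Array weights gave 254 (Boxer), 4222 (pacing) and 5280 (Boxer against pacing). They turned COL3A1 to -0.079 (pacing), and COL1A1 to -0.13 and PDK4 to 0.13 (between breeds). The GAPDH ratio as a covariate gave 95 (Doberman), 2935 (pacing), 56 (between breeds) and 1028 (Doberman against pacing). It turned CRYAB to -0.031, TTN to -0.12, MYH7 to -0.10, TRDN to -0.43, DSP to 0.31 and COL3A1 to 0.32 (Doberman). It turned COL3A1 to -0.11 and TRDN to 0.011 (pacing). Between breeds it turned TTN to -0.067, TRDN to -0.35 and DSP to 0.41. Leaving out L and R gave 376 (Doberman), 118 (Boxer), 4407 (pacing), 304 (between breeds), 2265 (Doberman against pacing) and 5126 (Boxer against pacing). It turned CRYAB to -0.13, TTN to -0.14, MYH7 to -0.24, TRDN to -0.41, COL3A1 to 0.99 and ITGB1 to 0.32 (Doberman). Between breeds it turned TTN to -0.053, ATP2A2 to -0.14, TRDN to -0.31, PDK4 to 0.65, DSP to 0.0078, COL3A1 to 0.49, CD36 to 0.38 and OGDH to 0.44. The filter at the 70th percentile, which tests fewer probe sets, gave 2157 (Doberman), 3 (Boxer), 220 (pacing), 2602 (between breeds), 1747 (Doberman against pacing) and 407 (Boxer against pacing). No filter gave 4389 (pacing), 5974 (Doberman against pacing) and 5720 (Boxer against pacing). Genes counted instead of probe sets, which are fewer, numbered 1358 (Doberman), 3 (Boxer), 480 (pacing), 1790 (between breeds), 1287 (Doberman against pacing) and 741 (Boxer against pacing). Lists past the threshold with the preset correlation numbered 6 (Doberman), 7 (Boxer), 1 (pacing), 4 (between breeds) and 5 (Doberman against pacing). In fry they numbered 10 (Doberman), 1 (Boxer), 6 (between breeds), 7 (Doberman against pacing) and 3 (Boxer against pacing). It gave the lymphocyte list, with a median of 0.094 (pacing), the opposite direction. Where a value above changed for other reasons than fewer probe sets, genes or samples, the cause was not tested.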

Other observations

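The values here were chosen only after the result was seen. Of the 13 samples, Doberman K had the highest values of the interferon response genes named here. On the log2 scale MX1 was at 12.72 in K and between 7.96 and 9.81 in the other 12 samples, MX2 at 10.84, OAS2 at 10.27, ISG15 at 11.15 and CXCL10 at 9.99. With Dobermans L and R left out, 6 of the 6 listed genes passed with a median of 2.99. Doberman K is 1 sample, assumed to vary like the other groups.

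The probe sets of ACTA1 moved apart. Of its 4 tested probe sets, 2 changed alike against the controls: 2.88 and 3.31 with pacing, 0.63 and 0.63 in the Boxers. Another had passed as lower in each of these comparisons, at -4.16 ± 0.30 in the Boxers, -3.03 ± 0.32 in the Dobermans and -1.26 ± 0.32 with pacing, and the last was at -0.42, 0.81 and -0.21 without passing. No sequence of the probes was used here.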
